A study of Mus musculus with 11 samples.

How the data were processed

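RNA was measured in 11 clonal lines of ER-Hoxb8 mouse granulocyte-monocyte progenitors, 6 wild-type (WT) and 5 tafazzin knockout (KO), grouped by the genotype given in the labels. Per the labels' protocols, the lines came from C57BL/6 fetal liver at embryonic day 15.5, grew with 0.5 uM beta-estradiol and about 50 ng/ml of stem cell factor, and gave total RNA from 5 M cells each. Libraries were polyA-selected and strand-specific, per the labels' protocols. The authors deposited raw counts per Ensembl gene, 1 set per clone, not normalised and not pooled. STAR, HTSeq and edgeR and the mouse build mm9 are named without versions, per the submitters' processing notes. The annotation release and the part of Taz that was deleted are not given in the sources used here. The deposited counts carry a mark that strand was ignored in counting, so reads from overlapping antisense genes cannot be told apart. Reads that match several places were left out of gene counts, which makes genes with near-identical copies, such as ribosomal protein genes, uncertain.

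Gene counts totalled 19778119 to 27431544 per clone. The counter's own totals, which name no gene, were kept out of library sizes and tests. Reads in no gene made up 6.07 ± 0.551% in WT and 6.59 ± 0.411% in KO clones, and ambiguous reads 2.85 ± 0.0581% and 2.79 ± 0.0737% (SD, n = 6 and 5), of gene counts and these 2 totals together. Alignment records that were not unique came to 83.6 and 86.3 per 100 gene counts. Of 37583 gene IDs, 32860 (87.4%, holding 99.6% of the counts) were matched to symbols by ID in a mouse annotation of another build (GRCm38), which was used only for names, chromosome, gene order, GC content and length. The symbols Hmgcs1, Bcl2a1a, Bcl2a1d, Hbb-b1 and Hbb-b2 were not matched, and genes of the mitochondrial genome were not analysed here. No pair of libraries of 1 genotype agreed within sampling noise (lowest chi-square per gene 15.0). Floors of 3 counts cover counting error only.

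The KO and WT clones were compared with edgeR's robust quasi-likelihood test on the counts, with TMM normalisation, filterByExpr and Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. CPM values use the TMM-scaled library sizes and log2 CPM a prior count of 2. Errors of fold changes are standard errors worked back from the test, as the absolute log2 fold change over the square root of its F statistic. The 2 title numbers within each genotype were compared in a model of 4 set means. Gene lists were tested with camera on the same fit (preset correlation 0.01, Benjamini-Hochberg over 36 lists with at least 3 tested members), with camera with an estimated correlation and with fry beside it. Each clone's list score is the mean of its members' centred log2 CPM. Scores, Taz, principal components and library measures were compared with two-sided exact permutation tests over all 462 splits of the clones, adjusted over the 36 lists for scores. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.

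The groups, tests, alternatives, 39 gene lists and the rule for named genes were fixed before the data were examined. The rule takes Taz, then the 8 higher and 8 lower called genes of largest fold change with a symbol, a mean of at least 5 CPM and no overlap between genotypes. From each list it takes up to 4 called members with the smallest adjusted p where camera calls the list, up to 2 where it does not, and the most abundant member where none is called. Called genes of the title-number contrasts, sex-linked genes and the genes of the construct are also named, and any member of the integrated stress response, endoplasmic reticulum, cardiolipin and BCL2 lists may be named. S100a8, Ltf, Ngp, Perp, Trp53, Slc1a4, Slc1a5, Slc6a6, Selenow and Scd1 were chosen after their values were seen. So were the permutation test of list scores, 4 alternatives (equal depth by thinning, GC content and length, the late neutrophil score and the Hoxb8 level as covariates) and 4 further lists. Some genes that the rule takes are not reported here.

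Other settings fixed in advance were RLE and upper-quartile normalisation, no filter and a stricter filter, DESeq2, limma-voom, a non-robust fit, the title number as a random block, as summed counts and as set means, leaving out each clone and each title number, and leaving out the 10 most abundant genes or the genes of X and Y. The tests were tried on simulated counts for the KO and WT comparison (6 against 5 clones, 11900 genes, 200 changed by these folds and 30 others shifted as a list). The totals of calls below include calls of those 30. Counts were drawn with the spread per gene that edgeR had estimated, which may favour edgeR. The folds were 1.5, 2 and 4, and edgeR recovered 58.2% of genes changed 1.5-fold, 71.6% at 2-fold and 90.9% at 4-fold, with 6 false calls among 168 (3.57%). DESeq2 made 42 false calls among 218 (19.3%) and limma-voom 7 among 162 (4.32%). On the same simulated counts camera in limma gave an unadjusted p of 6.02e-24 for the 30 genes shifted by 0.5 on the log2 scale, 0.116 for an unchanged list and values under 0.05 for 0% of 200 random unchanged lists. Simulated genes were drawn independently of each other. In the real data the estimated correlation within lists ran from -0.01 to 0.74. The simulation therefore cannot show how often camera's preset correlation gives false calls for lists whose genes vary together. A simulated contrast of the WT title numbers gave 0 false calls in edgeR.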

Results

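RNA was sequenced from 11 clonal lines of mouse granulocyte-monocyte progenitors (GMPs), the bone marrow and fetal liver precursors of neutrophils and monocytes. The lines came from fetal liver at embryonic day 15.5 and were conditionally immortalised with ER-Hoxb8, a fusion of the estrogen receptor's hormone-binding part with the transcription factor Hoxb8. This fusion keeps progenitors dividing and immature while estradiol is present, here at 0.5 uM. Each line was grown from a single cell. There were 6 wild-type (WT) clones and 5 knockout (KO) clones lacking tafazzin. Tafazzin, the product of Taz on the X chromosome, remodels cardiolipin, the characteristic phospholipid of the inner mitochondrial membrane, and its loss in people causes Barth syndrome, in which neutropenia is common. The titles also carry a number, 1 or 2 for WT and 3 or 4 for KO clones, whose meaning is not given in the sources used here. Whether clones of 1 number share a parent culture is therefore open, and p-values measure only the spread between these clones. The comparison asks how the transcriptome of undifferentiated progenitors differs when tafazzin is missing. Gene counts totalled 26071215, 27431544, 21966954, 23288919, 26829138 and 24227590 in WT clones 1A, 1B, 1C, 2D, 2E and 2F, and 19778119, 23572337, 23658158, 21293849 and 19913625 in KO clones 3H, 3I, 4J, 4K and 4L. WT libraries were deeper, at 24.97 ± 2.15 M gene counts (SD, n = 6) against 21.6 ± 1.90 M (SD, n = 5) in KO (two-sided exact permutation test, p = 0.0303).

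Taz itself (ENSMUSG00000009995) was measured first, as a check of the genotype labels. It stood at 39.1 ± 2.54 CPM (SD, n = 6) in WT clones and 3.23 ± 0.68 CPM (SD, n = 5) in KO clones, which is 8.25% of the WT level. Each KO clone lay between 2.21 and 4.09 CPM and each WT clone between 37.0 and 43.8 CPM, so all 11 libraries matched their labels. The log2 fold change was -3.60 ± 0.14 (SE), with an adjusted p of 4.08e-07 in edgeR's quasi-likelihood test. The two-sided exact permutation test gave p = 0.00216, the smallest that 462 splits of the clones can give. Between 44 and 87 reads per KO library were still assigned to the gene. The deleted part of the gene is not given in the sources used here, and counting ignored strand, so reads from remaining exons or an overlapping transcript would be included.

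Between genotypes, 601 of 11900 tested genes changed at an edgeR adjusted p under 0.05, of which 328 were higher and 273 lower in KO clones (54.6% higher). Most changes were small, with a median absolute log2 fold change of 0.30 among called genes, and 75 genes changed at least 2-fold (52 higher, 23 lower). For 501 of the 601, no KO clone overlapped any WT clone, and 5.99% of all tested genes separated in this way against 0.433% by chance. The count depended on the clones: it was 380, 316, 368 and 395 without WT 1A, 1B, 1C or 2F and 301, 240, 293, 373 and 325 without KO 3H, 3I, 4J, 4K or 4L. At least 2-fold changes numbered 42, 34, 42 and 46 without WT 1B or KO 3I, 4J or 4L. Only 32 to 296 genes were called when all clones of 1 title number were left out.

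**Figure D1:**
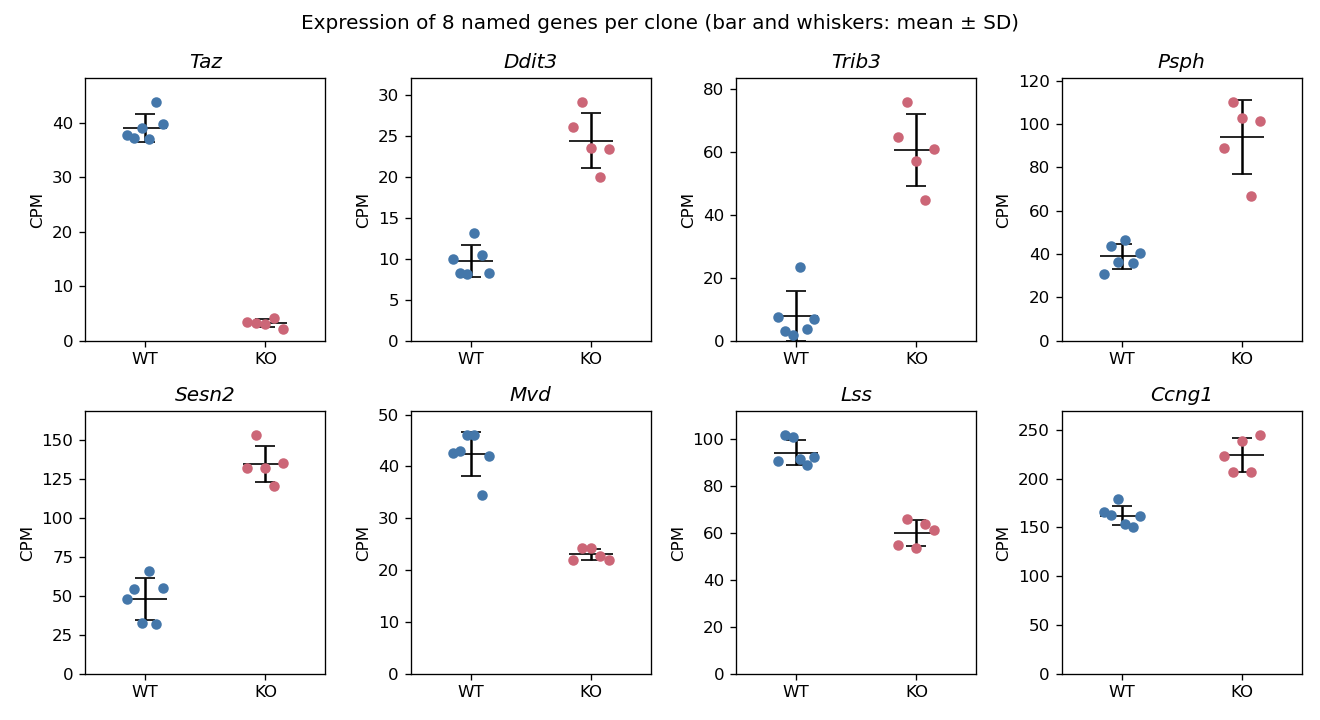
Normalised expression (CPM, vertical axes from 0) of 8 named genes in the 6 WT and 5 KO clones, with points for clones, a bar for the group mean and whiskers for the SD. Taz lies between 2.21 and 4.09 CPM in KO clones, and Ddit3, Trib3, Psph, Sesn2 and Ccng1 are higher and Mvd and Lss lower in KO clones, without overlap.

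Genes of the integrated stress response, the program in which phosphorylated eIF2alpha favours translation of the transcription factor ATF4, rose in KO clones. Of 31 tested targets, 20 rose and none fell, and all 31 had a positive fold change (median log2 fold change 0.76). Adjusted over the list alone, 30 rose. The count was 12, 13, 12, 12 and 12 without WT 1B or 2F or KO 3H, 3I or 4L. It was 4, 6 and 3 without all clones of title number 1, 3 or 4, 12 with counts summed per title number and 13 with set means. Ddit3, which encodes the stress transcription factor CHOP, rose from 9.66 ± 1.96 to 24.4 ± 3.39 CPM (SD), a log2 fold change of 1.34 ± 0.14 (SE; edgeR adjusted p = 0.00117). The serine synthesis enzyme Psph rose by a log2 fold change of 1.28 ± 0.14 (SE), the leucine sensor Sesn2 by 1.49 ± 0.18 and the ATF4 partner Cebpg by 0.52 ± 0.06. Larger rises were seen for Vldlr (3.07 ± 0.40), the pseudokinase Trib3 (2.97 ± 0.57) and Cth, an enzyme of cysteine synthesis (3.83 ± 0.86). Cth lost its call when any of 7 clones was left out (WT 1A, 1B or 2F, or KO 3H, 3I, 4J or 4L; highest adjusted p = 0.0746). The glutathione-degrading enzyme Chac1 (1.86 ± 0.42) lost it without any of 9 clones (all but WT 2D and 2E; highest adjusted p = 0.0849). Asparagine synthetase, Asns (1.04 ± 0.23), lost it without WT 1B or 2F or KO 3H, 3I, 4J or 4L (highest adjusted p = 0.0703). Atf4 (0.59 ± 0.16, adjusted p = 0.0621) and Atf5 (1.80 ± 0.56, adjusted p = 0.0939) were not called. Each passed the threshold in 7 of 31 alternative settings (adjusted p from 0.00118 to 0.362 for Atf4 and from 0.00163 to 0.428 for Atf5), and among omissions of 1 clone only without WT 2D (adjusted p = 0.00733 and 0.00279). Of 36 lists tested, 13 were called by camera, and 5 of them with an estimated correlation. The stress response list was called (adjusted p = 9.99e-42; adjusted p = 0.0328 with an estimated correlation), and its score per clone separated the genotypes (exact permutation test, p = 0.00433, adjusted p = 0.0312). WT 2D had the highest WT score (0.07, against -0.34 to -1.04 in the other WT clones and 0.44 to 0.85 in KO clones), and it also had by far the highest late neutrophil gene levels, given below with the cell type lists.

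Genes of the endoplasmic reticulum (ER) folding machinery were not called as a list and changed in both directions. Of 33 tested chaperone and ER-associated degradation genes, 4 rose and 3 fell (adjusted over the list alone, 5 and 7), with a median log2 fold change of -0.05 and camera adjusted p = 0.511 (0.849 with an estimated correlation). Herpud1 (0.35 ± 0.06, SE) and Sel1l (0.36 ± 0.07), parts of the degradation complex, rose, as did the stress sensor Ern1 (0.29 ± 0.06), which lost its call without KO 3H, 3I or 4J (highest adjusted p = 0.0593), and Derl1 (0.18 ± 0.04), which lost it without any clone but KO 4K (highest adjusted p = 0.108). The luminal chaperone Hsp90b1 (-0.34 ± 0.08) and the disulfide isomerase Pdia6 (-0.33 ± 0.08) fell, although each lost its call without any of 9 clones (all but WT 2D and 2E; highest adjusted p = 0.0900 and 0.0870). Syvn1 (-0.17 ± 0.04) lost it without any clone but WT 2E (highest adjusted p = 0.110), and without WT 2E 5 genes of the list were called lower. The chaperone Hspa5 had a log2 fold change of -0.23 ± 0.11 (edgeR adjusted p = 0.298) and Xbp1 one of -0.10 ± 0.13 (adjusted p = 0.737). Mitochondrial chaperones and proteases were not called (camera adjusted p = 0.783). Among their 15 tested genes only Hspa9 rose (0.35 ± 0.08), and it lost its call without any of 8 clones (all but WT 2D and 2E and KO 4K; highest adjusted p = 0.0817), while 2 were called higher without WT 2D.

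Cholesterol synthesis genes fell together. Of 22 tested genes of cholesterol synthesis and uptake, 18 fell and none rose, all 22 fell when adjusted over the list alone, and the median log2 fold change was -0.50. The count was 3, 8 and 3 without title number 1, 3 or 4 and 11 with counts summed per title number. The mevalonate enzyme Mvd fell from 42.4 ± 4.19 to 23.01 ± 1.12 CPM (SD), a log2 fold change of -0.88 ± 0.07 (SE; edgeR adjusted p = 0.000763). Lss fell by 0.65 ± 0.06, Nsdhl by 0.61 ± 0.06 and Dhcr7, which catalyses the last step, by 0.52 ± 0.07 on the log2 scale. The list was called by camera (adjusted p = 4.61e-35; adjusted p = 0.00579 with an estimated correlation), and its score was lower in every KO clone than in any WT clone (exact permutation test, p = 0.00216, adjusted p = 0.0260). Of 14 fatty acid synthesis genes, 3 fell: Acly (-0.32 ± 0.05), the desaturase Scd2 (-0.53 ± 0.09) and Fads2 (-0.42 ± 0.11). Adjusted over the list alone, 9 fell. The count was 0, 1 and 0 without title number 1, 2 or 4 and 6 with the late neutrophil score as a covariate. Fads2 lost its call without any of 9 clones (all but WT 1A and 2D; highest adjusted p = 0.110). Camera called this list (adjusted p = 1.60e-06), with adjusted p = 0.0568 with an estimated correlation, and the score test gave adjusted p = 0.0433. The list's mean log2 fold change was -0.51 against a median of -0.19. Its member Scd1, which was not called, had a log2 fold change of -4.43 and ranged from 0.207 to 73.1 CPM among WT clones. A score is a mean over members, so 1 such member can weigh heavily on it.

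Targets of the tumour suppressor p53 rose. Of 15 tested, 7 rose and none fell (9 adjusted over the list alone), with a median log2 fold change of 0.44. The count was 2, 4 and 2 without title number 1, 3 or 4 and 3 with counts summed per title number. Zmat3 rose from 2.13 ± 0.49 to 8.84 ± 2.84 CPM (SD; log2 fold change 2.05 ± 0.24, SE; edgeR adjusted p = 0.00156). The cell cycle inhibitor Cdkn1a rose by a log2 fold change of 0.74 ± 0.10, Ccng1 by 0.47 ± 0.06 and Bbc3, which encodes the pro-apoptotic protein PUMA, by 0.85 ± 0.10. Trp53 mRNA itself had a log2 fold change of 0.01 ± 0.03 (adjusted p = 0.851); it was chosen after its value was seen. Camera called the list (adjusted p = 8.40e-11; adjusted p = 0.00579 with an estimated correlation), and the score test gave adjusted p = 0.0390. WT 1A and 2D had the lowest p53 scores (-0.99 and -0.66, against -0.09 to 0.01 in the other WT clones), and the target Perp, also chosen after its values were seen, was at 0.0768 and 17.3 CPM in them against 225 to 419 CPM in the other 9 clones. The wider list of the BCL2 family and caspases was not called (camera adjusted p = 0.397). Of its 21 tested genes, 2 rose, Bbc3 and Bid, and 1 fell. Adjusted over the list alone, 4 rose and 3 fell. The count of higher genes was 1 without WT 1B, 1C or 2F or KO 3H, 3I, 4J or 4L, and that of lower genes 2 without WT 2D or KO 4L. Bid (0.21 ± 0.05) lost its call without any clone but WT 1A (highest adjusted p = 0.0919). The median of this list was -0.01 while its mean was 0.10 and its test direction was up.

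**Figure D2:**
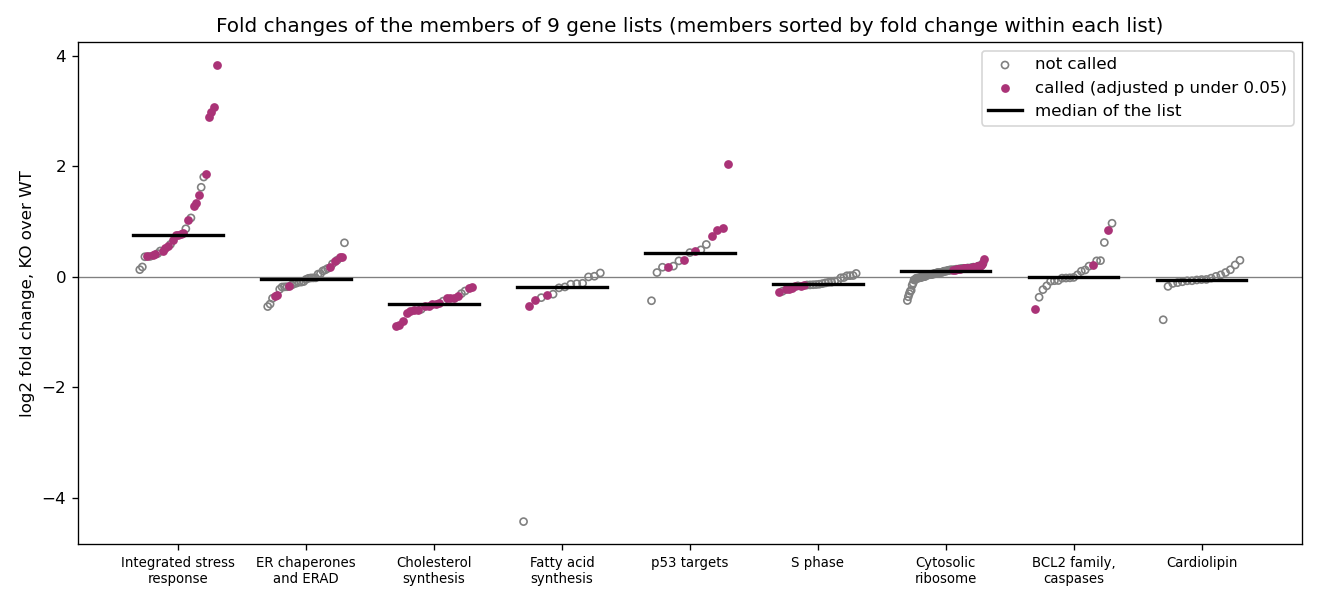
Log2 fold change of KO over WT (vertical axis) for each tested member of 9 gene lists, filled where edgeR called the gene at an adjusted p under 0.05 and open where it did not, with a bar at the list's median. The integrated stress response (median 0.76) and p53 targets (0.44) lie above 0, cholesterol genes (-0.50) below it, and ER chaperones (-0.05) spread to either side.

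Genes of cardiolipin metabolism other than Taz were not called as a list (17 tested, camera adjusted p = 0.737). Adjusted over the list alone 1 rose, the cardiolipin synthase Crls1 (0.30 ± 0.08, SE; edgeR adjusted p = 0.0503 over all genes). Crls1 passed the threshold over all genes in 9 of 31 alternative settings (adjusted p from 0.00737 to 0.299). Among omissions of 1 clone it passed without WT 2D (adjusted p = 0.0202) or KO 4K (0.0234). The most abundant of this list, Phb2, had a log2 fold change of -0.17 ± 0.11 (adjusted p = 0.391). ATP synthase genes were lower as a list, with 2 of 15 called lower and 3 adjusted over the list alone (median -0.07; camera adjusted p = 0.00115, but adjusted p = 0.447 with an estimated correlation; score test adjusted p = 0.0312). Atp5k fell by 0.25 ± 0.04 on the log2 scale and Atp5g3 by 0.16 ± 0.04, the latter losing its call without WT 1A, 1B or 1C or KO 3H, 3I or 4K (highest adjusted p = 0.0755). The call of the ATP synthase list ended after a correction for GC content and gene length (median -0.06, adjusted p = 0.0698). Camera also called complexes II and III (2 of 14 genes lower, adjusted p = 0.0328), the citric acid cycle (2 of 20 lower, 0.0328), mitochondrial ribosomal proteins (2 of 76 lower, 0.0270) and glycolysis (2 lower and 1 higher of 22, 0.0282). Adjusted over the list alone, 6, 3, 2 and 4 genes of these lists were lower and 1, 0, 0 and 1 higher. With an estimated correlation these 4 lists had adjusted p = 0.654, 0.581, 0.835 and 0.654, and their score tests gave adjusted p = 0.239, 0.239, 0.557 and 0.213. Each of these calls ended without WT 2D (adjusted p = 0.212, 0.147, 0.495 and 0.141) or KO 4K (0.185, 0.186, 0.260 and 0.0656). The calls of the first 3 also ended without KO 3I (0.0692, 0.0692 and 0.0712), that of mitochondrial ribosomal proteins without WT 1A (0.139) and that of glycolysis without WT 2F (0.0805) or KO 4J (0.0626). The first 3 calls also ended after the GC and length correction (adjusted p = 0.327, 0.110 and 0.301; medians from -0.09 to -0.06, from -0.06 to -0.05 and from -0.06 to -0.04) and with the late neutrophil score as a covariate (adjusted p = 0.313, 0.262 and 0.755), and all 4 ended with the Hoxb8 level as a covariate (0.231, 0.197, 0.765 and 0.233). Of the genes of complexes II and III, 0 of 14 were called lower without WT 1A, 1B, 1C or 2F or any KO clone, and 1 without WT 2D. In the citric acid cycle 1 gene was called lower without WT 1B, 1C, 2E or 2F or KO 3H, 3I, 4K or 4L, and among mitochondrial ribosomal proteins 1 without WT 1A, 1B or 2F or KO 3H, 3I, 4J or 4L. In glycolysis 1 gene was called lower without KO 3I, and 0 were called higher without WT 1B or 1C or KO 3H, 3I or 4J. Examples that kept their calls without any 1 clone were Fh1 (-0.15 ± 0.03), Mrpl34 (-0.19 ± 0.03) and lactate dehydrogenase, Ldha (-0.35 ± 0.06). Complex I (adjusted p = 0.109), complex IV (0.594), cristae and fusion genes (0.511), fatty acid oxidation (0.0827), hypoxia targets (0.156), antioxidant genes (0.737) and autophagy genes (0.800) were not called by camera. Of the genes in these lists, 2 of 16 hypoxia targets, 1 of 18 complex IV genes and 1 of 22 autophagy genes were called lower (adjusted over the list alone, 2, 1 and 2, with 0, 1 and 1 higher). These counts depended on the clones. The hypoxia count was 1 without WT 1A or 2E or KO 3H, 4J, 4K or 4L and 0 without KO 3I. The complex IV count was 0 without WT 1A, 1B, 1C or 2F or KO 3H, 3I, 4K or 4L, and the autophagy count 0 without WT 1A or 2E or KO 3H, 3I, 4J or 4K. Of 23 antioxidant genes 2 were called higher and 2 lower (3 and 3 adjusted over the list alone). Here 1 was called higher without WT 1B, 1C, 2E or 2F or any KO clone, and 1 was called lower without WT 1A or KO 3H, 4J or 4K and 0 without KO 3I. Complex I passed the threshold in 4 of 30 other settings, among them leaving out KO 4J (adjusted p = 0.0248) or 4L (0.0450). Fatty acid oxidation passed in 6 of 30, among them leaving out WT 1A (0.0360) or 2D (0.0232), and hypoxia targets in 1 (0.0113). In edgeR's test over all genes Etfdh of fatty acid oxidation fell (-0.30 ± 0.05), and of the antioxidant list Gclc (0.22 ± 0.03) rose while Prdx1 (-0.20 ± 0.04) fell, the last losing its call without KO 3H or 3I (highest adjusted p = 0.0617). Without title number 3 or 4, 0 genes were called lower in the lists of ATP synthase, complexes II and III, complex IV, the citric acid cycle, mitochondrial ribosomal proteins, glycolysis, fatty acid oxidation, hypoxia, antioxidants and autophagy. The same held without title number 1, except for 1 gene each in ATP synthase and glycolysis. Genes of the mitochondrial genome were not analysed here.

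Genes of DNA replication were slightly lower and cytosolic ribosomal protein genes slightly higher in KO clones. Of 26 S-phase genes, 7 fell and none rose (10 adjusted over the list alone; median -0.14), including the helicase subunit Mcm4 (-0.18 ± 0.03, SE; edgeR adjusted p = 0.0154). The count was 3 without KO 3H, 3I or 4J, 4 without KO 4K or title number 2, and 0 without title number 1, 3 or 4 and with counts summed per title number. The list held under camera (adjusted p = 5.32e-07; adjusted p = 0.00843 with an estimated correlation) and in the score test (adjusted p = 0.0260). Of 21 G2 and M-phase genes, Cdc20 and Kif20a fell and Top2a rose, but each call depended on the clones. Cdc20 lost it without any clone but WT 2D, WT 2E or KO 4L, Kif20a without any but WT 2E or KO 4L, and Top2a without any (highest adjusted p = 0.111, 0.108 and 0.105). Adjusted over the list alone, 7 fell and 1 rose. That list was called by camera (adjusted p = 1.84e-05), with adjusted p = 0.447 with an estimated correlation and 0.0433 in the score test. Of 81 cytosolic ribosomal protein genes, 22 rose and none fell (36 and 2 adjusted over the list alone), with a median log2 fold change of 0.10. The count was 8, 8 and 9 without WT 1A, 1B or 1C and 7, 9, 12, 14 and 8 without KO 3H, 3I, 4J, 4K or 4L. It was 1, 8, 1 and 1 without title numbers 1, 2, 3 and 4, 1 with counts summed per title number, 6 with no filter, 9 with set means and 8 with the Hoxb8 level as a covariate. Rps20 rose by a log2 fold change of 0.21 ± 0.03 and Rps15a by 0.20 ± 0.03. Camera called this list (adjusted p = 5.55e-09), with adjusted p = 0.263 with an estimated correlation and 0.0433 in the score test. Ribosomal protein genes have many processed pseudogenes, and reads matching several places were left out of the counts, so these values are uncertain. Nucleolar ribosome biogenesis genes were not called by camera (adjusted p = 0.109), nor were replication histones (0.594). The ribosome biogenesis list passed in 8 of 30 other settings, among them leaving out WT 1A (0.0360), WT 2D (2.62e-05) or KO 4K (0.0275).

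Lists of markers of most blood lineages were not called. Primary granule genes (camera adjusted p = 0.397), progenitor genes (0.420), monocyte and dendritic cell genes (0.511), basophil, mast cell and eosinophil genes (0.517), erythroid and megakaryocyte genes (0.192), liver, stromal and endothelial genes (0.326), interferon-stimulated genes (0.0994), NF-kappaB targets (0.737) and immediate-early and heat-shock genes (0.397) were not called by camera. Interferon-stimulated genes passed in 6 of 30 other settings, among them leaving out WT 2E (adjusted p = 0.00582), KO 4J (0.0186) or KO 4L (0.00494). Erythroid and megakaryocyte genes passed in 3 of 30 (lowest adjusted p = 0.00499), primary granule genes in 2 (0.0263) and immediate-early and heat-shock genes in 1 (0.0234). Among NF-kappaB targets, the prostaglandin synthase Ptgs2 rose (0.78 ± 0.14). The median and mean of the NF-kappaB list were negative while its test direction was up. The myeloperoxidase gene Mpo stood at 9989 ± 2517 CPM (SD) in WT and 9387 ± 3240 CPM in KO clones. Late neutrophil genes were not called (camera adjusted p = 0.0645; exact permutation test of the score, p = 0.396). S100a8, Ltf and Ngp, chosen after their values were seen, were at 438, 137 and 242 CPM in WT 2D against at most 42.0, 3.27 and 8.11 CPM in any other WT clone and 30.1, 5.17 and 11.2 CPM in any KO clone. The list passed camera's threshold in 9 of 30 other settings (lowest adjusted p = 0.000357). Among these were set means (adjusted p = 0.0387) and leaving out WT 1C (0.0330), WT 2E (0.00473), KO 4J (0.0182) or KO 4L (0.0154). Without WT 2D it had adjusted p = 0.740. Lymphoid genes were lower in KO clones: 1 of 13 was called lower (4 adjusted over the list alone; median -1.04), namely the B cell receptor component Cd79b, at 8.55 ± 7.24 CPM (SD) in WT and 0.61 ± 0.22 CPM in KO. Cd79b lost its call without KO 3I (adjusted p = 0.0562). The count of called lymphoid genes was 0 without title number 1, 3 or 4, with set means and with the Hoxb8 level as a covariate, 2 without WT 2E or title number 2, with counts summed per title number and with the late neutrophil score as a covariate, and 3 without WT 2D. The list was called by camera (adjusted p = 0.000168; 0.0351 with an estimated correlation) and by the score test (adjusted p = 0.0260).

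**Figure D3:**
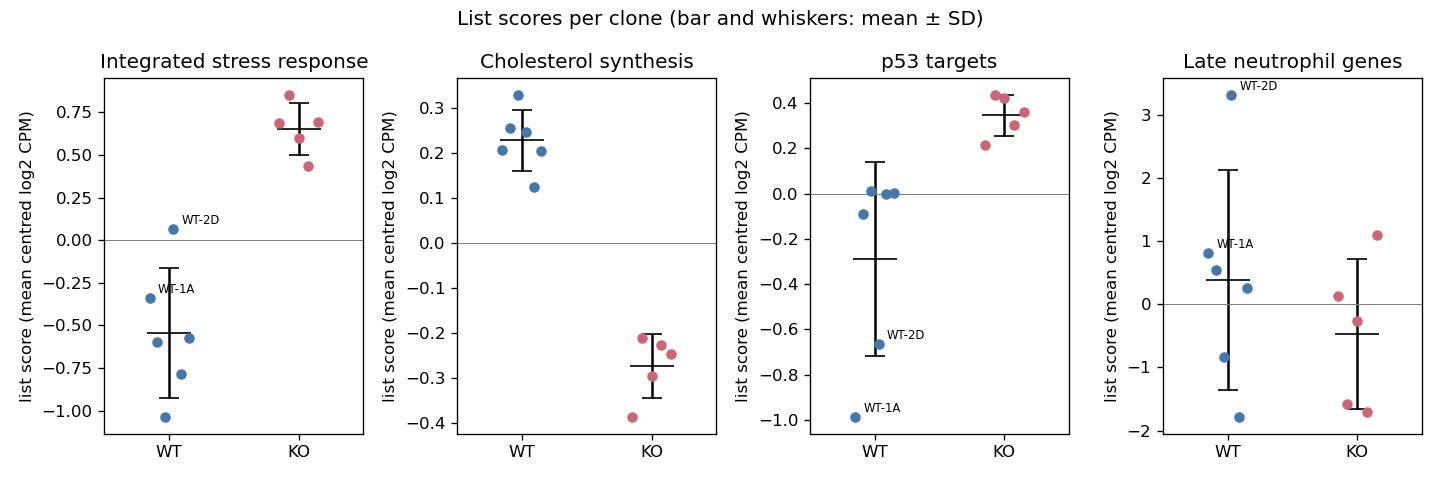
List scores (mean centred log2 CPM over the tested members, vertical axes) of 4 gene lists in the 6 WT and 5 KO clones, with points for clones, bars for means and whiskers for SDs. The integrated stress response, cholesterol and p53 scores do not overlap between genotypes, while the late neutrophil score does, with WT 2D highest at 3.32.

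Among called genes other than Taz with a mean of at least 5 CPM over all 11 clones and no overlap of genotypes, the 8 largest rises were Extl1 (log2 fold change 4.46 ± 0.56, SE), Cth, Tenm4 (3.79 ± 0.85), Cox6a2 (3.72 ± 0.33), Bcat1 (3.68 ± 0.64), Vldlr, Trib3 and Slc6a9 (2.44 ± 0.41). Cox6a2, the muscle form of a cytochrome c oxidase subunit, went from 2.13 ± 1.02 to 28.2 ± 4.79 CPM (SD; edgeR adjusted p = 0.000763). Bcat1 breaks down branched-chain amino acids and Slc6a9 carries glycine. By the same limits the 8 largest falls were Mzb1 (-3.75 ± 0.85), Tspoap1 (-2.95 ± 0.64), Plag1 (-2.43 ± 0.47), Gm45837 (-2.18 ± 0.44), glutamine synthetase, Glul (-1.91 ± 0.46), Camk2a (-1.53 ± 0.22), Myo7a (-1.39 ± 0.26) and the integrin gene Itgb3 (-1.06 ± 0.23). Calls of several of these depended on the clones. Tenm4 lost its call without WT 1B, 1C or 2F or KO 3I, 4J or 4K (highest adjusted p = 0.0809) and Itgb3 without WT 1B, 1C or 2F or KO 3H, 4J or 4L (0.0732). Mzb1 lost it without any clone but WT 1C, 2D or 2E (0.0791), Tspoap1 without WT 1A or any KO clone (0.0780) and Glul without any clone but WT 1C or KO 3H (0.108). Plag1 and Gm45837 lost it without KO 3I or 4J (0.0517 and 0.0633 at most), Myo7a without KO 3I (0.0529) and Cth as given above. WT clones varied widely for Mzb1 (11.2 to 159 CPM) and Tspoap1 (51.5 to 689 CPM).

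All 11 clones expressed Y-linked genes, and Xist had 0 to 2 reads per library. Tsix had 0 reads in every library, which allows a level of up to 0.109 to 0.152 CPM at a floor of 3 counts. Ddx3y was at 103 ± 4.45 CPM (SD) in WT and 119 ± 2.84 CPM in KO (edgeR adjusted p = 0.00980), Eif2s3y at 87.3 ± 4.34 and 94.7 ± 3.55 CPM (0.140) and Kdm5d at 45.2 ± 3.38 and 47.0 ± 2.43 CPM (0.659). Uty was at 0.728 CPM in WT 1C and between 47.5 and 64.8 CPM in the other 10 clones. Hoxb8 and Esr1, whose reads can come from the ER-Hoxb8 transgene, were highest in WT 2D (254 and 303 CPM). They did not differ by genotype beyond the spread (135 ± 62.5 against 93.9 ± 18.5 CPM, adjusted p = 0.333, and 167 ± 71.7 against 123 ± 23.7 CPM, adjusted p = 0.382).

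Clones of the 2 title numbers within a genotype were also compared. Between WT clones numbered 2 and 1, 0 genes were called in edgeR's test (372 genes, 3.13%, at an unadjusted p under 0.05; 12 called by DESeq2), and between KO clones numbered 4 and 3 also 0 (161 genes, 1.35%; 5 called by DESeq2). Leaving out WT 1C or KO 4J gave 1 call in the respective contrast. The median correlation across genes was 0.958 for clones of the same number, 0.963 for clones of the same genotype with another number and 0.955 across genotypes; genes are not independent replicates. The first principal component (30.7% of variance) did not separate the genotypes (exact permutation test, p = 0.121), with WT 2D and 1A at its low end, where S100a8 and Ngp had large weights. Scores on the second (15.7%) differed between genotypes (exact permutation test, p = 0.00649), with WT 2D among the KO clones.

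**Figure D4:**
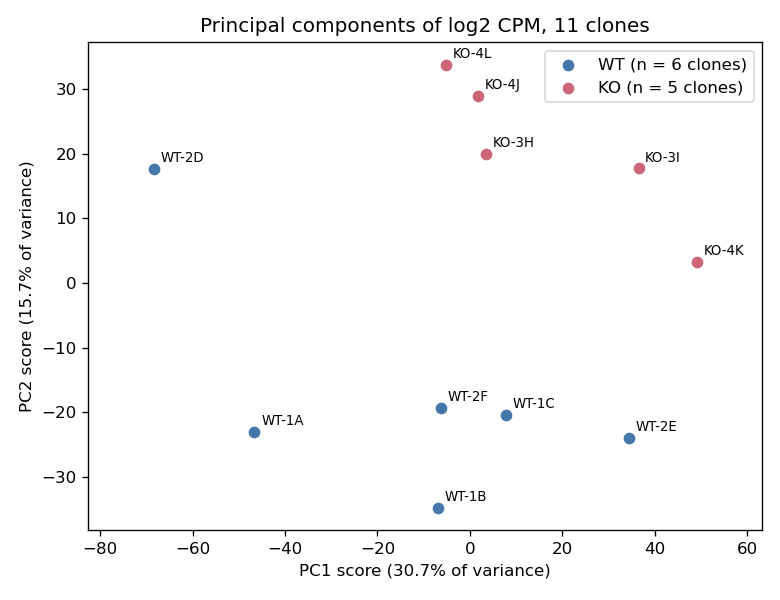
Scores of the 11 clones on the first principal component (horizontal axis, 30.7% of variance) and the second (vertical axis, 15.7%) of log2 CPM, with points for clones, coloured by genotype. WT 2D and 1A lie farthest to the left, and 5 of the 6 WT clones lie below all KO clones.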

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

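All tests of explanations below were chosen after the results were seen, except the counts of genes, 2-fold genes, lists with a preset correlation and WT title-number calls over other splits of the clones, which were planned.

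Among 100 splits of the 11 clones into 6 and 5, the real one included, only 1, the real split, gave as many called genes (601, highest other 3). The same held for genes at 2-fold (75, highest other 1). Chance can be excluded for these counts if the clones are independent. Each genotype has its own title numbers, which may mark shared cultures. Splits of single clones cannot exclude differences between such sets. For the 13 lists called by camera with its preset correlation chance cannot be excluded, since 38 of 100 splits gave as many and the highest other gave 22. With an estimated correlation only the real split, 1 of 100, gave as many lists (5, highest other 1). Chance can be excluded for that count too, again only if the clones are independent. For WT clones numbered 2 against 1, 10 of 10 splits gave as many genes (0, highest other 1), and these splits are too few for a share under 0.05.

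Targets of the integrated stress response were higher in KO clones, with a median log2 fold change of 0.76. GC content with gene length and maturing neutrophils were argued against as the whole cause. The median was 0.77 after the GC and length correction and 0.85 with the late neutrophil score as covariate. After thinning to equal depth it was 0.76. Random thinning keeps each gene's expected share of a library, so this median could hardly move and decides nothing about library depth. Against folding load in the endoplasmic reticulum as a candidate source, 10 folding genes had a mean log2 fold change of -0.20 ± 0.064 (SE over genes), with 0 called higher and 2 lower. Genes measured in the same clones are not independent replicates, so this SE does not measure the spread between clones. Folding load was still left undecided, because those 10 leave out 4 members called higher (Herpud1, Sel1l, Ern1 and Derl1), and all 33 tested chaperone and degradation genes had a median of -0.047 with members called in both directions. Differences in culture or harvest between the sets of clones were not tested and stay open beside an effect of the genotype.

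Cholesterol genes were lower in KO clones, with a median log2 fold change of -0.50. The median was -0.51 after the GC and length correction and -0.53 with the late neutrophil score as covariate, which argues against each of these as the whole cause. After thinning to equal depth it was -0.49, which for the reason given above decides nothing about library depth. Medium, serum lots and cell density were not tested and stay open beside the genotype.

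Targets of p53 were higher in KO clones, with a median log2 fold change of 0.44, while WT 1A and 2D had the lowest scores. The median was 0.43 after the GC and length correction, which argues against these gene properties as the whole cause. After thinning it was 0.45, which again decides nothing about library depth. For this list the median with the late neutrophil score as covariate was not weighed. Camera with its preset correlation still called the list higher with that covariate, which alone does not decide, so maturing neutrophils stay open. WT 1A and 2D also had the highest late neutrophil scores among WT clones (0.81 and 3.32). Leaving out the 4 members that the stress response may also raise gave a median of 0.30 over the other 11 (5 called higher; camera p = 1.67e-08, p = 0.000699 with an estimated correlation), which is below the bound set for excluding this explanation and leaves it undecided. WT 1A and 2D as the whole cause were argued against, since the lowest KO score lay 0.20 above the highest of the other 4 WT clones (SD of these 4, 0.047). Camera with its preset correlation called the list without any 1 clone, WT 1A and 2D included (highest adjusted p = 1.14e-09). Each such omission keeps WT 1A or 2D or both, and that setting also called many lists in other splits, so these calls add little. Differences in culture or harvest were not tested and stay open beside the genotype.

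Single clones stood apart from the rest of their group in 29 of 286 groups of values tested, 9 of them in WT 2D. Dixon's ratio was used, the gap to the nearest clone over the range, with limits of 0.71 for 5 clones and 0.625 for 6. Chance sets apart about 1 in 20 groups only where values are independent and normally distributed. Genes were tested as CPM, which was strongly skewed for some, and all groups come from the same 11 clones. Whether 29 exceeds chance is therefore undecided. Several of the genes set apart were chosen after their values were seen. In WT 2D, S100a8 was at 438 CPM (other WT clones 0.0736 to 42.0), Ltf at 137 (0 to 3.27), Ngp at 242 (0.0736 to 8.11), Atf5 at 96.7 (10.7 to 33.6), Trib3 at 23.4 (1.77 to 7.53), Slc6a9 at 9.64 (1.46 to 3.71), Hoxb8 at 254 (69.6 to 133) and Esr1 at 303 (91.9 to 164), and the autophagy score was -0.15 (0.01 to 0.07). In KO 4L, S100a8 was at 30.1 CPM (other KO clones 0.141 to 7.87), Ltf at 5.17 (0 to 0.965) and Ngp at 11.2 (0 to 2.44), and the lymphoid score was -1.28 (-0.57 to -0.30). In KO 4K, Cth was at 39.7 CPM (113 to 135), Sel1l at 226 (273 to 285), Atf4 at 518 (626 to 651) and Ern1 at 198 (220 to 229), and the NF-kappaB score was 0.23 (-0.13 to -0.03). In KO 4J, Tspoap1 was at 35.8 CPM (26.96 to 29.5) and Ddx3y at 124 (117 to 118), and the fatty acid oxidation score was -0.10 (-0.02 to -0.01). Scd1 was at 73.1 CPM in WT 2E (0.207 to 16.6) and 3.44 in KO 3I (0.0425 to 0.753). Mvd was at 34.6 CPM in WT 2E (42.1 to 46.0), Trp53 at 266 in KO 3I (249 to 254) and Nsdhl at 50.9 in KO 3H (59.1 to 60.9). Bcat1 was at 25.01 CPM in WT 2F (2.21 to 6.18), Zmat3 at 3.09 in WT 1B (1.73 to 2.09) and Uty at 0.728 in WT 1C (47.5 to 59.5).

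Alignment records that were not unique, which no comparison of genes uses, came to 86.3 ± 1.24 per 100 gene counts in KO clones and 83.6 ± 0.94 in WT clones (SD, n = 5 and 6; two-sided exact permutation test, p = 0.00649).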

How the results depend on the processing

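The settings with equal depth, GC and length, the late neutrophil score and the Hoxb8 level were chosen after the results were seen. Taz was called in all 30 settings run for it (log2 fold change -3.70 to -3.49). For 103 other named genes, 2542 of 3184 values kept their side of the threshold, 612 lost and 30 gained a call, and 0 turned direction. Changes of sign in genes called in neither setting were not counted as turned. Such genes included S100a8, Ltf and Ngp, which were called in no setting and whose log2 fold changes took either sign across settings. Of 79 called genes, 8 kept the call in every setting run, and 39 lost it without some clone. For lists, 994 of 1080 values kept their side, 46 lost and 40 gained a call, and 0 turned by the same rule. Changes of direction in lists called in neither setting were not counted as turned. The integrated stress response, cholesterol, p53, S-phase and lymphoid lists were called in every setting run. Of 601 called genes, 599 were shared under RLE, 598 under DESeq2 and 562 under limma-voom. Without 1 clone, 240 to 739 genes were called, 34 to 101 of them at 2-fold, and 0 to 1 in each title-number contrast. Leaving out title numbers 1, 2, 3 and 4 gave 45, 296, 92 and 32 genes, with 13, 25 and 8 at 2-fold for numbers 1, 3 and 4, and 75% higher for number 4. Counts summed per title number gave 197 genes (49 at 2-fold), of which 115 were among the 601. These settings have fewer samples. With no filter, 329 were called among 21266 tested, a larger number to adjust over. For the following the cause was not tested: DESeq2 called 1265 genes (195 at 2-fold) and 12 and 5 in the WT and KO title-number contrasts. Set means called 307 (48) and the late neutrophil covariate 959 (120), while 5 lists were called with an estimated correlation and 8 by fry, also with no test of the cause. The random block called 1983 genes (240 at 2-fold), with a block correlation of -0.21. A negative block correlation lowers the modelled error of the genotype difference, so this larger count is not stronger evidence. No paired analysis was possible because the genotypes share no replicate numbers. KO libraries were shallower; thinned to equal depth, 587 genes were called, 548 of them among the 601. Fewer were called after the GC and length correction (439, of which 394 among the 601) and with the Hoxb8 level as covariate (411, of which 341), and the cause was not tested. The GC and length correction also ended the list calls of ATP synthase, complexes II and III, the citric acid cycle and mitochondrial ribosomal proteins.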

Other observations

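The lists, genes and tests below were chosen after the results were seen. Genes of amino acid transport and of cytosolic tRNA charging were higher in KO clones. Of 18 tested plasma membrane amino acid transporters, 8 rose and 1 fell (camera adjusted p = 4.03e-08 over these 4 lists; adjusted p = 0.0218 with an estimated correlation). The neutral amino acid carrier Slc1a4 rose from 31.6 ± 8.55 to 77.3 ± 6.17 CPM (SD, n = 6 and 5; edgeR adjusted p = 0.00268), and Slc1a5, which carries glutamine, rose by a log2 fold change of 0.61 ± 0.12 (SE), losing its call without KO 3I or 4J (highest adjusted p = 0.0568). The taurine transporter Slc6a6 fell by 0.53 ± 0.08 on the log2 scale. Of 20 cytosolic aminoacyl-tRNA synthetases, 7 rose and 0 fell (camera adjusted p = 2.11e-08; adjusted p = 0.266 with an estimated correlation), while the 17 mitochondrial ones were not called as a list (camera adjusted p = 0.541). Some members of the transport and cytosolic synthetase lists are also members of the integrated stress response list, so these results are not independent of it. Of 19 selenoprotein genes, 3 rose and 2 fell (camera adjusted p = 0.541), and Selenow rose from 18.1 ± 1.82 to 30.5 ± 2.29 CPM (SD; edgeR adjusted p = 0.00106).

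The median log2 fold change of the 40 tested genes nearest to Taz on the X chromosome, 20 on each side, was -0.01. Scd1 had a log2 fold change of -4.43 ± 1.32 (SE; edgeR adjusted p = 0.0859) and ranged from 0.207 to 73.1 CPM among WT clones.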
